A study of Arabidopsis thaliana with 12 samples.

How the data were processed

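RNA from 5-day-old Arabidopsis thaliana seedlings was sequenced in 12 samples, which per the labels form 4 groups of 3: wild-type Col-0 and the nup1-1 mutant, each grown on MS medium without treatment or on MS medium supplemented with abscisic acid (ABA). NUP1 encodes a nuclear pore protein. The labels do not state the ABA dose or whether the 3 samples of a group came from separate plates or sowings. Any spread between samples behind the p-values may thus be technical. How the deposited test estimated that spread for each gene is not given in the sources used here.

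The submitters' processing notes name FastQC, Trimmomatic, TopHat and the genome build TAIR10, and versions are not given in the sources used here. The values used were 4 gene-level comparison tables of 33201 rows each, with the same genes in the same order. Per the file headers, each table holds 1 value per group and gene, a log2 fold change, a test statistic, a p-value and a q-value; the program that wrote them is not given in the sources used here. The authors deposited the group values as FPKM: among the lowest values above 0, longer gene models had lower values, as division by length gives. The deposited test statistic is a score that was rescaled below. The deposited q-values were equal to a Benjamini-Hochberg adjustment of the deposited p-values over the genes marked as tested, and the smallest deposited p was 5e-05 in each table.

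No value per library was used, because each table holds a single value per group. The authors' group values are therefore printed without an SD or an n. Total counts per library were not used here, so the depth of single samples is unknown. For the lowest values above 0 a low percentile was taken rather than the minimum. In gene models with 4000 to 5000 exon bases it was 0.0033, 0.0029, 0.0036 and 0.0029 FPKM in the Col-0 untreated, Col-0 ABA, nup1-1 untreated and nup1-1 ABA groups. In gene models of 2000 to 2400 exon bases it was 0.0078, 0.0072, 0.0109 and 0.0073 FPKM. The length bins thus differ in how the groups compare, and relative depth was not read from them.

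Each table had been normalized separately. Over genes above 1 FPKM, the Col-0 ABA group was 0.20 higher on the log2 scale in the genotype table than in the ABA table, and the nup1-1 untreated group was lower there by a median of -0.20, with SDs across genes of 0.0016 and 0.0011. Levels of a group are therefore printed with the table they come from and are not compared between tables. The difference of the ABA responses, the overlaps, the covariances and the simulations with shared libraries set fold changes of separately normalized tables side by side. The values of 130 plastid and 141 mitochondrial rows were listed at 0 in all tables and were not analysed here. Genes for which the tables mark the estimate as failed from too many reads (LHCB1.3, RBCS1A and RBCS3B) are listed at 0 there and were left out of those comparisons. A further 286 rows join several neighbouring gene models; NUP50A and 2 proteasome genes lie in such rows and were left out of the lists. Of the row names, 32196 matched a locus tag of the TAIR10.1 reference, which gave symbols; coordinates are those of the authors' tables on TAIR10, with the start counted from 1.

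Genes were called changed at a deposited q under 0.05 among genes marked as tested. Log2 fold changes were recomputed from the deposited FPKM values. Standard errors were reconstructed: the deposited statistic times a factor, fitted per table between 1.738 and 1.743 so that its normal p matches the deposited p, gives the normal deviate, and the fold change divided by it gives the standard error. For genes near 0 in a group the deposited p can be larger than this deviate gives; the p-based error was over 1.5 times the reconstructed one for 294, 469, 119 and 172 genes of the Col-0 ABA, nup1-1 ABA, untreated genotype and ABA genotype tables. The standard errors of such genes are too small, so for those named in the 4 comparisons the q-value is printed instead.

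Whether the ABA response differs between genotypes was tested per gene by a 2-sided Wald test of the difference of the log2 fold changes of both ABA tables, which share no library, with Benjamini-Hochberg adjustment over 19487 genes tested in both and at 1 FPKM or more in the highest of the 4 groups. This test is approximate, since it rests on reconstructed standard errors and the normal distribution; its adjusted value is also called q. In data simulated for this test over 18826 genes, 38% of changes of log2 size 1 and 86% of size 2 were recovered, and 4.6% of calls were unchanged genes. The noise was drawn from the same reconstructed standard errors, in genes with standard errors of at most 1 and with few genes changed. These shares thus check the calculation and do not estimate the share of false calls in the real data. Overlaps of calls are given beside the product of the list sizes divided by the genes tested in both. Covariances and correlations across genes used genes with standard errors of at most 1.

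There were 17 gene lists with 386 members, of which 364 reached 1 FPKM in the highest group and are called measured. For each list the text gives the members past the q threshold over all genes, the number past 0.05 when adjusted over the list alone, and the median of log2((FPKM + 1)/(FPKM + 1)), which understates the change of low genes. The percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins, describes these libraries and is not a p. In the check of this step, 6% of 100 random lists fell outside the central 95%.

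The rule for named genes took NUP1 and ABI5 always, the 6 highest and 6 lowest log2 fold changes among called genes with at least 5 FPKM in the higher group and a value above 0 in both, and up to 4 called members per list with the largest change. For the difference of the ABA responses it took the 5 highest and 5 lowest, and list members named for that test were picked after their values were seen. Groups, tests, lists, the naming rule and most alternatives were set before the data were examined; genes outside the rule are named as such. Alternatives were a threshold of 0.01, a minimum log2 fold change of 1, a minimum of 1 FPKM, normal p-values from the statistic, other standard errors and filters for the difference of responses, and a pseudocount of 0.1, centring and no FPKM filter for the lists. Wider standard errors, exchanged spreads and the threshold of 0.01 for named genes were added after the data were seen. The ABA comparison in Col-0 and the genotype comparison on ABA, which share the Col-0 ABA libraries, were set against 100 simulations with no genotype effect. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.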

Results

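The transcriptomes of Col-0 and nup1-1 seedlings were measured at 5 days on medium with and without ABA, a hormone that holds back germination and seedling growth, in 4 groups of 3 samples. The series names NUP1, the nuclear pore, the proteasome and ABI5, a bZIP transcription factor of the ABA response, as its subject. The authors' deposited tables give 1 FPKM value per group, so errors below are standard errors of log2 fold changes reconstructed from the deposited statistics, and q-values are those the tables hold. Between 20004 and 20459 genes were tested per comparison. Log2 fold changes of the 12 reference genes ranged from -0.72 to 0.71 over the 4 comparisons. None of them was called for ABA in Col-0 or for genotype in untreated seedlings, where none had an unadjusted p under 0.05 either. ACT2 and UBQ5 were called in both comparisons that include nup1-1 on ABA, and the UBQ5 call for genotype on ABA was lost when adjusted over the list alone.

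NUP1 (AT3G10650, chromosome 3, 3325170 to 3330892) was still transcribed in the groups labelled nup1-1. In the authors' deposited table for untreated seedlings it stood at 12.8 FPKM in Col-0 and 9.23 FPKM in nup1-1, a log2 difference of -0.47 ± 0.23 that did not pass the test (q = 0.243). On ABA it stood at 13.8 FPKM in Col-0 and 7.47 FPKM in nup1-1, and this difference of -0.88 ± 0.15 was called in the authors' deposited table (q = 0.000272). ABA left NUP1 without a call in Col-0, with 12.7 FPKM untreated and a log2 fold change of -0.08 ± 0.22 (q = 0.911), and lowered it in nup1-1 from 10.6 to 7.53 FPKM (q = 0.0038 in the authors' deposited table). The Wald test of the difference of these log2 ABA responses, -0.41 ± 0.27, did not pass (q = 0.356), so a different ABA effect on NUP1 between the genotypes was not shown. A value per gene does not say which part of the transcript the reads cover, so these levels alone do not check the mutant label.

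ABI5 (AT2G36270, chromosome 2, 15204764 to 15207528) rose on ABA in both genotypes. The authors' deposited table gave 2.15 and 32.8 FPKM for Col-0, a 15.3-fold rise, and 2.72 and 73.4 FPKM for nup1-1, a 27.0-fold rise. The untreated genotype difference of ABI5 was 0.13 ± 0.31 on the log2 scale and did not pass the test (q = 0.895), while on ABA nup1-1 had 72.9 FPKM against 37.7 FPKM in Col-0, 1.93-fold more (q = 0.000272 in the authors' deposited table). The difference of the log2 ABA responses, 0.82 ± 0.33, did not pass its own test (q = 0.0676).

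**Figure D1:**
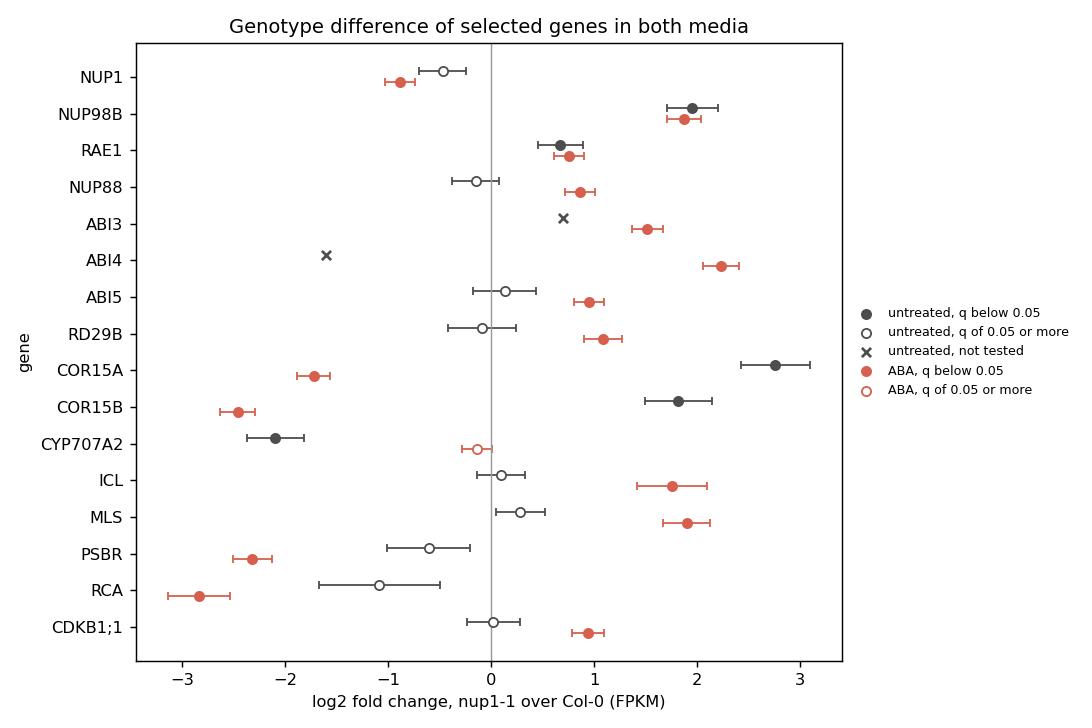
Log2 fold changes of 16 genes, nup1-1 over Col-0, from the authors' FPKM values in untreated seedlings (grey) and on ABA (red), for genes picked for display. Bars are reconstructed standard errors, filled points have q below 0.05, open points do not, and crosses were not tested; NUP98B lies at 1.95 untreated and 1.87 on ABA, while COR15A moves from 2.76 untreated to -1.72 on ABA.

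The first question is how ABA changed the wild type. In Col-0, ABA raised seed maturation genes, genes of lipid reserve use and ABA response genes, and lowered nuclear photosynthesis genes. How far the ABA-grown seedlings had germinated is not given in the sources used here. Changes within cells and a retained seed stage can therefore not be told apart in the ABA response of either genotype. The seed storage and late embryogenesis list had 25 of 28 measured members higher and 1 lower, DOG1, a dormancy gene named after its value was seen (25 and 2 adjusted over the list alone), with a median log2 fold change of 6.71. In the authors' deposited table the tonoplast aquaporin gene TIP3;1 rose from 0.912 to 410 FPKM and LEA76, a late embryogenesis abundant protein gene, from 1.77 to 862 FPKM. Of 40 measured nuclear photosynthesis genes, 35 were lower (40 adjusted over the list alone) and none was higher, also at an unadjusted p under 0.05, with a median of -1.05. In total 3174 of 20329 tested genes were called in Col-0, 1591 higher and 1583 lower (1018 and 786 with a log2 fold change of at least 1).

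Within the ABA receptor and core signalling list, 11 members rose, 3 fell and 16 did not pass the test in Col-0 (15 higher and 7 lower adjusted over the list alone). The phosphatase genes HAI3, AHG1 and HAI2, negative regulators of the pathway, rose by 7.25 (q = 0.0118), 5.80 ± 0.58 and 5.19 ± 0.45 on the log2 scale, and ABI3, a transcription factor of seed maturation, by 6.44 ± 0.40. ABI4 stood at 0.0781 and 7.18 FPKM in the authors' deposited table without a call (q = 0.141). In the ABA and dehydration list 20 of 25 rose and none fell (22 higher and none lower adjusted over the list alone; none lower at an unadjusted p under 0.05). RD29B rose by 8.06 ± 0.27, RAB18, a dehydrin gene, by 6.87 ± 0.25, TSPO by 7.32 ± 0.31 and KIN1 by 5.54 ± 0.25; KIN1 and KIN2 are near-identical neighbours whose reads the counting could split. The ABA catabolism genes CYP707A1, CYP707A3 and CYP707A2 rose 11.8-fold, 3.91-fold and 2.31-fold, and no member of the synthesis and catabolism list fell, against 1 lower at an unadjusted p under 0.05 (3 higher and 1 lower adjusted over the list alone).

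The fatty acid beta-oxidation and glyoxylate cycle list, of reserve mobilisation, had 10 of 16 members higher and none lower in Col-0 (13 higher adjusted over the list alone; none lower at an unadjusted p under 0.05), with a median of 1.07. The glyoxylate cycle genes MLS and ICL rose from 7.52 to 551 FPKM and from 28.5 to 1739 FPKM in the authors' deposited table. PCK1, which encodes phosphoenolpyruvate carboxykinase, rose 5.22-fold and MFP2, a peroxisomal beta-oxidation gene, 4.78-fold. Cell division genes were higher in 12 of 28 cases and lower in none (17 higher adjusted over the list alone; none lower at an unadjusted p under 0.05), among them CYCB2;2 with 1.22 ± 0.26, AUR2 with 1.08 ± 0.24 and CDKB1;1 with 0.91 ± 0.24.

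The photosynthesis members with the largest falls in Col-0 were LHCB2.2 (-1.72 ± 0.25), PSAF (-1.63 ± 0.28), LHCB2.1 (-1.55 ± 0.26) and PSAN (-1.55 ± 0.27); reads of LHCB2.1 and LHCB2.2 may be split between these copies. Among expansin and xyloglucan enzyme genes 6 rose and 4 fell of 22 (8 and 5 adjusted over the list alone), with EXPA8 falling from 106 to 14.5 FPKM and EXPA1 from 344 to 56.8 FPKM in the authors' deposited table. Gibberellin pathway genes rose in 5 of 19 cases and fell in 1, the same adjusted over the list alone: the DELLA repressor genes RGL2 and RGL3 rose 3.94-fold and 3.75-fold, and GASA6 fell by 1.58 ± 0.22. No nuclear pore or proteasome gene was called in Col-0; at an unadjusted p under 0.05 there were 0 of 32 and 1 of 49. Root hair and endodermis markers had 4 of 16 higher, stomatal lineage markers 1 of 6 lower (FAMA), and salicylic acid and defence genes 2 of 9 lower (PR5 and PAD4), all the same adjusted over the list alone. Heat shock genes had 1 of 12 higher (HSP70B), and of 8 regulators of ABI5 turnover ABD1 alone was called, at 1.56-fold; both calls were lost when adjusted over the list alone.

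The highest fold changes in Col-0 were those of the glycine-rich protein gene AT5G35660, the glucosidase gene BGLU19, the late embryogenesis genes AT5G44310 and AT4G36600, GASA3 and the lectin gene AT3G21380, between 735-fold and 1464-fold in the authors' deposited table. The lowest were AT4G12490, GSTF14, AT3G16670, the glutaredoxin gene AT2G47880, GLP9 and PEPC1, with log2 fold changes between -5.50 and -4.06. Untreated values from 0.0916 to 0.239 FPKM stand behind the highest folds, and BGLU19, GASA3 and AT5G35660 had q-values of 0.0497, 0.0315 and 0.0237, so those folds are imprecise.

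The next comparison asks how ABA changed nup1-1. In the mutant too ABA raised seed maturation, reserve use and cell division genes, and lowered nuclear photosynthesis genes. In total 9528 of 20459 tested genes were called, 4342 higher and 5186 lower (1692 and 2794 with a log2 fold change of at least 1), at a median standard error of 0.18 beside 0.24 in Col-0. All 42 measured photosynthesis genes fell, with a median of -2.13, and 26 of 28 cell division genes rose, with a median of 0.97; both counts were the same adjusted over the list alone. The seed storage and late embryogenesis list had 22 of 28 members higher and 1, DOG1, lower (25 higher and 1 lower adjusted over the list alone), with a median of 7.14. In the authors' deposited table LEA76 rose from 1.24 to 2644 FPKM and the oleosin gene OLEO2, for a coat protein of oil bodies, from 1.13 to 2262 FPKM.

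Reserve mobilisation genes rose in 15 of 16 cases in nup1-1 (15 adjusted over the list alone) and fell in none, also at an unadjusted p under 0.05. MLS rose from 10.5 to 2379 FPKM and ICL from 35.2 to 6798 FPKM in the authors' deposited table, and MFP2 and PCK1 rose 12.5-fold and 11.3-fold. The largest photosynthesis falls were those of PSBR (-2.84 ± 0.28), RCA, the gene of Rubisco activase (-2.79 ± 0.44), LHCA1 (-2.76 ± 0.32) and LHCB2.1 (-2.63 ± 0.20). CDKB1;1 rose 3.56-fold, AUR2 3.18-fold, CYCB2;4 2.71-fold and CYCB2;2 2.66-fold. Root hair and endodermis markers rose in 8 and fell in 3 of 16 cases, the same adjusted over the list alone, with WOX5, a gene of the root stem cell niche, at 3.06 ± 0.32 and EXPA7 at 1.59 ± 0.16.

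The ABA receptor and core signalling list had 15 members higher and 9 lower of 30 in nup1-1, and these counts were the same adjusted over the list alone. HAI3, ABI3 and AHG1 rose by 8.18 (q = 0.00336), 7.26 ± 0.33 and 6.86 ± 0.49. In the ABA and dehydration list 15 rose and 3 fell of 25, also adjusted over the list alone: RD29B rose by 9.25 ± 0.27, TSPO by 9.08 ± 0.30 and RAB18 by 8.02 ± 0.25, while COR15B, COR15A and RD22, which were named after their values were seen, fell, with log2 fold changes of -3.63, -1.45 and -0.91. COR15A and COR15B encode chloroplast proteins known from the cold response, and as close copies they may share reads. Of the ABA synthesis and catabolism list 5 rose and 3 fell, the same adjusted over the list alone. CYP707A1 and CYP707A2 rose 15.2-fold and 9.02-fold, and BGLU18, a glucosidase gene linked to ABA release, fell from 29.7 to 4.45 FPKM in the authors' deposited table. Defence genes fell in 6 of 9 cases, among them PR5 (-4.15 ± 0.54), WRKY70 (-4.01 ± 0.30) and WRKY33 (-2.61 ± 0.19), and rose in 1, the same adjusted over the list alone. Of the stomatal lineage, FAMA fell (-1.70 ± 0.19) while TMM and SPCH rose 1.63-fold and 1.61-fold, and all 3 calls stayed when adjusted over the list alone.

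Nuclear pore genes rose in 11 of 32 cases in nup1-1 on ABA, and NUP1 fell (10 higher and 1 lower adjusted over the list alone). NUP88 rose by 1.14 ± 0.16 on the log2 scale, NUP35 1.86-fold, NUP50B 1.73-fold and NUP43 1.63-fold. Proteasome genes rose in 14 of 49 cases (11 adjusted over the list alone) and fell in none, also at an unadjusted p under 0.05; PBD1 rose 1.98-fold and RPT5B 1.90-fold, and the list's median was 0.26. Of the ABI5 turnover regulators, ABD1 rose 1.45-fold and SIZ1 fell by 0.50 ± 0.15, the same 2 adjusted over the list alone. RGL2 rose 14.5-fold and GASA6 fell by 3.82 ± 0.18 among 7 rising and 5 falling gibberellin genes of 19. Of 22 expansin and xyloglucan enzyme genes 9 rose and 9 fell (11 and 9 adjusted over the list alone), and heat shock genes rose in 6 of 12 cases and fell in 1; the heat shock and gibberellin counts were the same adjusted over the list alone.

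The largest rises in nup1-1 were those of TIP3;1, AT1G04560, AT1G65090, HVA22B, AT2G42560 and LEA76, between 2132-fold and 3130-fold in the authors' deposited table. The largest falls were those of AT1G67865, CYP706A6, AT1G67860, AT2G32870, the iron reductase gene FRO6 and the kinase gene CIPK20, with log2 fold changes between -7.72 and -6.86; AT1G67860 and AT1G67865 are neighbouring copies that may share reads. Untreated values from 0.0869 FPKM in AT1G65090, which had a q of 0.0418, to 1.24 FPKM in LEA76 stand behind the rises.

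**Figure D2:**
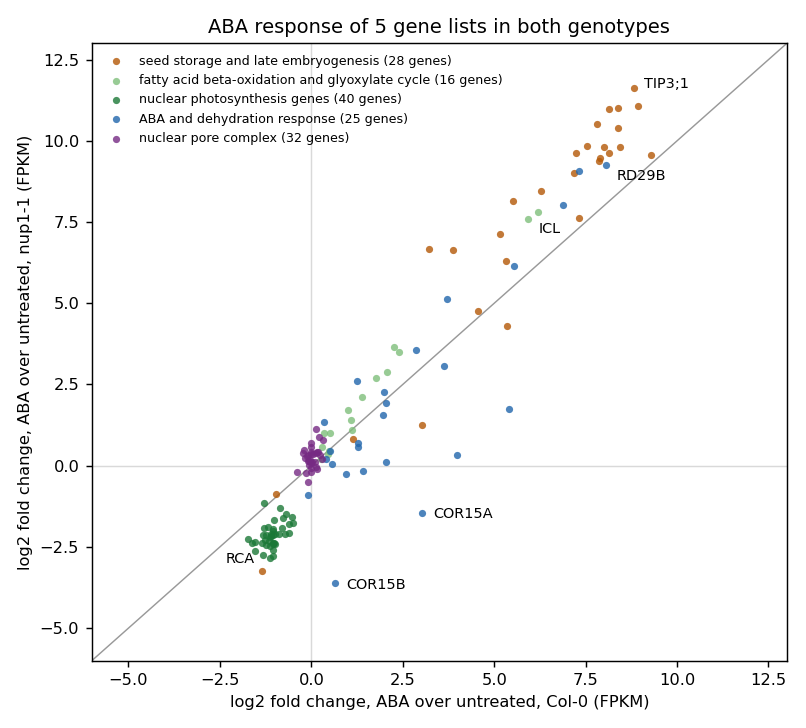
Log2 fold changes on ABA in Col-0 (horizontal axis) and nup1-1 (vertical axis), from the authors' FPKM values, for measured members of 5 gene lists; each point is a gene and the line marks equal responses. Most seed storage genes lie above the line, photosynthesis genes have medians of -1.05 in Col-0 and -2.13 in nup1-1, and COR15A and COR15B lie above 0 in Col-0 and below 0 in nup1-1.

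Whether the ABA response itself differed between the genotypes was tested gene by gene. Seed storage genes rose further in nup1-1, photosynthesis genes fell further, and several dehydration genes that rose in Col-0 rose less or fell in nup1-1. Of 19487 genes, 3181 differed, 911 with the higher and 2270 with the lower response in nup1-1; of the latter, 2018 were genes that ABA lowered in nup1-1. Among genes that ABA raised in Col-0, 249 had a higher and 284 a lower response in nup1-1, and among genes that it lowered, 66 and 600. These genes were picked by the Col-0 change that the difference subtracts. Picking alone thus moves raised genes toward a lower response and lowered genes toward a higher one, by an amount that was not computed. The seed storage list had 18 of 28 members with a higher and 2 with a lower response in nup1-1 (18 and 2 adjusted over the list alone), the photosynthesis list 22 of 40 lower and none higher (33 lower adjusted over the list alone), and the reserve mobilisation list 7 of 16 higher and none lower (9 higher adjusted over the list alone). The photosynthesis list had none higher and the reserve list none lower at an unadjusted p under 0.05 either. Of 28 cell division genes, 2 had a higher response in nup1-1 and 0 a lower one, against 7 and 0 at an unadjusted p under 0.05. Adjusted over the list alone, 0 cell division genes were called, and their median difference was 0.42. The seed list's median genotype difference was -0.66 untreated and 0.44 on ABA, and lower untreated values in nup1-1 are thus part of its larger response; CRA1 had 1.81 ± 0.40 in this test, beside a genotype difference of -1.97 ± 0.33 untreated and no genotype call on ABA. Members of lists are named for this test after their values were seen. MFP2 differed by 1.39 ± 0.30 (q = 9.3e-05), MLS by 1.62 ± 0.38 (q = 0.000283) and PSBR by -1.70 ± 0.40 (q = 0.000396).

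The dehydration list went both ways in this test, with 5 higher and 8 lower of 25 (6 and 8 adjusted over the list alone). RD29B differed by 1.19 ± 0.38 and TSPO by 1.76 ± 0.44, while COR15A differed by -4.48 ± 0.34, COR15B by -4.27 ± 0.33, GOLS2 by -3.65 ± 0.46 and RD20 by -3.65 ± 0.50. Core signalling genes had 2 higher and 5 lower of 30 (4 and 5 adjusted over the list alone). The receptor genes went both ways: PYL7 (-1.64 ± 0.43), PYL8 (-1.14 ± 0.28) and PYL5 (-1.11 ± 0.29) were lower and PYL2 (1.28 ± 0.43) was higher. The other higher member was EEL (1.35 ± 0.34). Defence genes had 0 higher and 3 lower of 9, the same adjusted over the list alone, against 1 higher at an unadjusted p under 0.05. WRKY70 and WRKY33 differed by -3.68 ± 0.41 and -2.93 ± 0.34. Expansin and xyloglucan enzyme genes had 8 higher and 5 lower of 22 (9 and 9 adjusted over the list alone). Among them XTH22 differed by -1.99 ± 0.29 and XTH31 by 1.25 ± 0.28. Untreated nup1-1 had higher levels of COR15A (2.76 ± 0.33), RD20 (2.29 ± 0.49) and WRKY33 (4.59-fold), which is part of their differences. For GOLS2 the higher untreated level (3.73 ± 0.47) was close in size to its whole difference. On ABA its genotype difference was 0.08 ± 0.16 without a call. NUP88 was the sole nuclear pore gene called, at 1.02 ± 0.27 (q = 0.00223), also adjusted over the list alone, and 0 of 49 proteasome genes were called, against 4 at an unadjusted p under 0.05.

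By size, the rule named AT4G22485 (-9.67 ± 2.13), AT2G44130 (-8.06 ± 1.17), AT4G22513 (-7.40 ± 2.19), AT1G76960 (-6.99 ± 1.53) and AT3G16670 (-6.64 ± 2.21) as lowest. The highest were AT1G65090 (4.23 ± 1.54), AT3G58450 (3.85 ± 1.34), AT3G14880 (3.69 ± 1.36), AT1G03106 (3.65 ± 0.91) and the late embryogenesis gene M10 (3.43 ± 0.96). With standard errors taken from the deposited p where these were wider, an alternative added after the data were seen, 2931 of the 3181 genes were called, but of those 10 only AT2G44130, an F-box protein gene, was (q = 0.000348). With the spreads of the genotype comparisons, AT1G65090 and AT3G58450 were not called either. Genes named after their values were seen, and called with either error, include CYP79F1, of glucosinolate synthesis, at -5.64 ± 0.51, MLP328 at -5.62 ± 0.52 and the esterase gene CXE13 at 3.42 ± 0.34. The seed storage list kept 13 higher and 1 lower member with the wider errors.

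Genes called on ABA in both genotypes went mainly the same way. Among 20090 genes tested in both, 1196 rose in both and 1357 fell in both, beside 337 and 397 for independent lists of these sizes. A further 110 rose in Col-0 and fell in nup1-1, against 404 for independent lists, and 13 fell in Col-0 and rose in nup1-1, against 331. Across 19068 genes, which are not independent replicates, the responses had a covariance of 0.851, Pearson's r = 0.774 and Spearman's rho = 0.589. Among genes called higher in Col-0 and lower in nup1-1, with at least 5 FPKM in a group, the largest differences were those of AT3G58550, the acyltransferase gene FACT, COR15A, AT1G52000, COR15B and AT4G21650, all named after their values were seen.

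In untreated seedlings the comparison asks what the nup1-1 genotype changes without added ABA. Some seed storage and photosynthesis genes were lower, some dehydration genes were higher, and the nuclear pore genes NUP98B and RAE1 were higher in nup1-1. NUP98B stood at 1.96 FPKM in Col-0 and 7.59 FPKM in nup1-1 in the authors' deposited table, 3.88-fold higher (q = 0.00198), and RAE1, of messenger RNA export, was 1.59-fold higher (q = 0.0411); the nuclear pore list had these 2 of 32 higher, also adjusted over the list alone, and none lower, against 1 at an unadjusted p under 0.05. COR15A was 6.76-fold higher, COR15B 3.53-fold, RD20 4.90-fold and GOLS2, of raffinose sugar synthesis, 13.3-fold. In total 1321 of 20004 tested genes were called, 536 higher and 785 lower (341 and 360 with a log2 fold change of at least 1).

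The ABA and dehydration list had 6 of 25 members higher and none lower in untreated nup1-1 (8 higher and 2 lower adjusted over the list alone; 3 lower at an unadjusted p under 0.05). HAI2, at 0.183 and 0.756 FPKM in the authors' deposited table, was the sole core signalling gene called (q = 0.0484), and this call was lost when adjusted over the list alone. Seed storage genes were lower in 5 of 28 cases (13 adjusted over the list alone), with the cruciferin gene CRA1 at -1.97 ± 0.33, OLEO2 at -1.72 ± 0.43 and SESA3 at -1.46 ± 0.40; SESA genes are clustered copies that may share reads, and SESA3 stood at 4.16 and 1.51 FPKM in the authors' deposited table. Photosynthesis genes were lower in 5 of 40 cases (12 adjusted over the list alone), with FD2, a ferredoxin gene, at -1.41 ± 0.33, PSAN at -1.33 ± 0.34 and PETC at -1.02 ± 0.33, and a list median of -0.67. No photosynthesis gene was higher, also at an unadjusted p under 0.05.

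Hormone genes changed in small numbers in untreated nup1-1. CYP707A2, the ABA 8'-hydroxylase gene of seeds, was lower, with 8.04 FPKM in Col-0 and 1.88 FPKM in nup1-1, and so was ABA1, of ABA synthesis, with 132 and 65.8 FPKM in the authors' deposited table, while BGLU18 was 2.47-fold higher (3 higher and 2 lower adjusted over the list alone). GA3OX2 was lower (-1.41 ± 0.29) and GA20OX2 was 2.41-fold higher, both genes of gibberellin synthesis, also adjusted over the list alone. WRKY33 and WRKY70 were 4.59-fold and 2.80-fold higher, the 2 defence genes called, also adjusted over the list alone. XTH22 was 1.99-fold higher, while XTH31 (-0.97 ± 0.24), EXPA1 (-0.95 ± 0.25) and EXPA10 (-0.74 ± 0.22) were lower; the expansin and xyloglucan enzyme list had 2 higher and 3 lower of 22 (4 and 5 adjusted over the list alone).

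Several lists had no call in untreated seedlings. No member was called among 49 proteasome genes, 8 regulators of ABI5 turnover, 28 cell division genes, 16 reserve mobilisation genes, 12 heat shock genes, 16 root hair and endodermis markers and 6 stomatal lineage markers in the authors' deposited table. At an unadjusted p under 0.05 these lists had 1, 1, 2, 2, 2, 3 and 2 members; adjusted over the list alone, 1 heat shock gene was higher and 2 stomatal lineage markers were lower. Some of these lists were still shifted as a whole. The medians of reserve mobilisation (0.29), cell division (0.18) and ABI5 turnover genes (0.24) lay at percentiles 100, 99.7 and 98.6 of matched lists. The stomatal lineage median of -0.29 lay at 1.5, and the heat shock and root hair lists at 22.5 and 87.2. The proteasome median of -0.04 lay at percentile 98.7 of matched lists, most of which had lower medians. Its sign and its percentile thus point in different directions.

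The highest genes in untreated nup1-1 were CORI3, a cystine lyase gene, at 14.3-fold, AT5G44260, LTP4, AT5G44440, SEN1 and LSU3, a low-sulfur response gene, at 7.40-fold. The lowest were the joined gene model of AT5G24240 and AT5G24250 at -5.19 ± 0.57, AT2G15020 at -5.08 ± 0.33, AT4G07820 at -4.59 (q = 0.0132), NEET, an iron-sulfur protein gene, at -4.24 ± 0.27, GSTF14 at -3.75 ± 0.32 and QQS, a gene linked to starch content, at -3.64 ± 0.50. NEET stood at 465 FPKM in Col-0 and 24.6 FPKM in nup1-1 in the authors' deposited table.

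On ABA the comparison asks where nup1-1 differs from Col-0 under the hormone. Photosynthesis genes were lower in nup1-1 in 41 of 41 measured cases, with a median of -1.83, while reserve mobilisation genes were higher in 14 of 16, cell division genes in 21 of 28 and nuclear pore genes in 21 of 32 (41, 15, 21 and 23 adjusted over the list alone). RCA stood at 4030 FPKM in Col-0 and 564 FPKM in nup1-1 in the authors' deposited table, and PSBR (-2.32 ± 0.19), RBCS1B (-2.30 ± 0.17) and PSAN (-2.13 ± 0.17) were lower. MLS, MFP2 and ICL were 3.73-fold, 3.54-fold and 3.38-fold higher and PCK1 2.72-fold. Called genes numbered 7873 of 20327 tested, 3131 higher and 4742 lower, and with a log2 fold change of at least 1 they were 599 and 2182, which takes the share higher from 39.8% to 21.5%.

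The core signalling list split evenly, with 8 higher and 8 lower of 30 (8 and 10 adjusted over the list alone). ABI4 stood at 8.24 FPKM in Col-0 and 38.7 FPKM in nup1-1 in the authors' deposited table, 4.70-fold higher, ABI3 was 2.86-fold and AHG1 2.84-fold higher, and the receptor gene PYL7 was lower (-1.61 ± 0.29). The dehydration list split likewise, 8 and 8 of 25, also adjusted over the list alone: COR15B (-2.46 ± 0.17), COR15A (-1.72 ± 0.16) and RD20 (-1.36 ± 0.21) were lower, and TSPO was 2.55-fold higher. Of the seed storage list 17 were higher and 8 lower of 28, the same adjusted over the list alone; M10 was 7.30-fold higher, while DOG1 (-3.22, q = 0.000962) and the 2S albumin genes SESA2 (-2.89 ± 0.21) and SESA5 (-2.71 ± 0.20) were lower.

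Among nuclear pore genes NUP98B was 3.66-fold higher on ABA, NUP88 1.82-fold and RAE1 1.69-fold, and NUP1 was the sole member lower (23 higher and 1 lower adjusted over the list alone). Proteasome genes were higher in 2 of 49 cases, RPT5B at 1.62-fold and RPN8B at 1.43-fold (2 adjusted over the list alone), and lower in none, also at an unadjusted p under 0.05. KEG, a ubiquitin ligase gene that acts on ABI5, was 1.41-fold higher and the sole call of 8 turnover regulators, also adjusted over the list alone. CDKB1;1 and CYCB2;3 were 1.92-fold and 1.94-fold higher, and CYCD3;2, named after its value was seen, was the 1 cell division gene that was lower, also adjusted over the list alone. Root hair genes EXPA7 and EXPA18 were 2.49-fold and 2.44-fold higher among 6 higher and 2 lower of 16 markers (6 and 3 adjusted over the list alone). The stomatal genes MUTE (-1.48 ± 0.34), EPF1 (-1.07 ± 0.27) and FAMA (-0.92 ± 0.18) were lower, the same 3 adjusted over the list alone.

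Gibberellin genes on ABA comprised 4 higher and 5 lower of 19 (4 and 6 adjusted over the list alone), with RGL3 and RGL2 2.54-fold and 2.45-fold higher and GASA6 lower (-2.70 ± 0.17). Of the ABA synthesis and catabolism list, AAO3 was 1.68-fold higher, and BGLU18 (-1.94 ± 0.18) and ABA1 (-0.80 ± 0.15) were lower, among 2 higher and 3 lower (2 and 4 adjusted over the list alone). Defence genes had 1 higher and 4 lower of 9, with WRKY70 at -2.20 ± 0.28 and EDS1 at -1.06 ± 0.17, heat shock genes 3 higher and 1 lower of 12 (4 and 1 adjusted over the list alone), and expansin and xyloglucan enzyme genes 7 and 7 of 22; defence and expansin counts were the same adjusted over the list alone. The lowest genes by size were CYP706A6, AIR1, CIPK20, PPT2, CYP79F1 and XTH6, between -6.32 and -5.63, and the highest PNP-A at 19.2-fold, AT1G72570, LCR67, AT2G17850, FOLB3 and M10. LCR67, a defensin-like gene, stood at 36.7 FPKM in Col-0 and 317 FPKM in nup1-1 in the authors' deposited table.

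**Figure D3:**
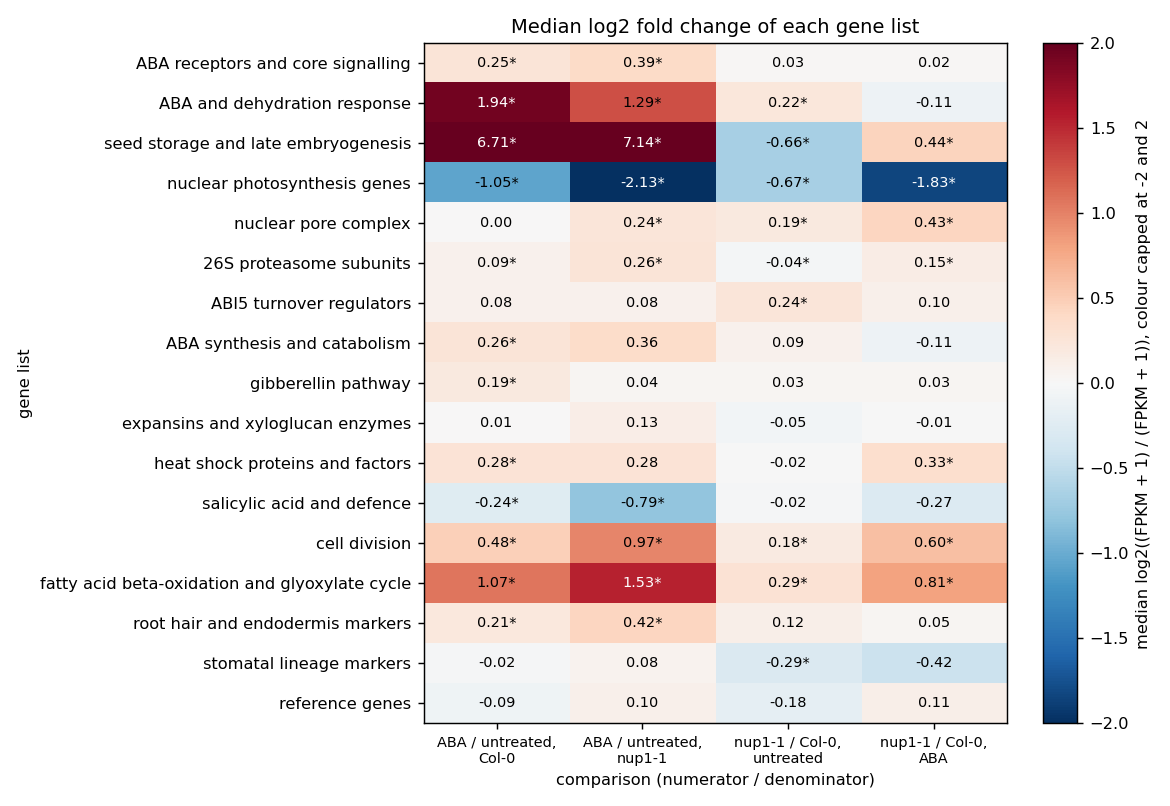
Median log2((FPKM + 1)/(FPKM + 1)) of the measured members of 17 gene lists in the 4 comparisons, with the median printed in each cell and colour capped at -2 and 2. An asterisk marks a median outside the central 95% of 10000 random lists matched on mean expression; the photosynthesis list lies at -1.83 and the nuclear pore list at 0.43 for nup1-1 over Col-0 on ABA.

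The genotype difference was partly shared between the media, mostly among lower genes. Of 19629 genes tested in both, 572 were lower in nup1-1 in both media, beside 183 for independent lists, and 99 were higher in both, beside 75.0. Another 226 were higher in untreated and lower in ABA-grown nup1-1, beside 121, and 41 went from lower to higher, beside 113. These comparisons share no library; across 18865 genes, which are not independent replicates, their covariance was 0.0873, Pearson's r = 0.232 and Spearman's rho = 0.240.

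On ABA, genes lowered by the hormone in Col-0 were mostly lower still in nup1-1, while genes raised by it went both ways. Over the 1591 genes that ABA raised in Col-0, the median log2 difference between nup1-1 and Col-0 on ABA was 0.29, with 726 called higher and 284 called lower in nup1-1. Over the 1583 genes that ABA lowered the median was -0.87, with 28 called higher and 1129 called lower. Independent lists would give 241, 376, 226 and 352 for these 4 counts. The ABA comparison in Col-0 and the genotype comparison on ABA share the Col-0 ABA libraries, which pushes them apart: simulations with no genotype effect gave medians of -0.05 and 0.07 over 18826 genes, where the observed medians were 0.31 and -1.14. The covariance was 0.200 beside a simulated -0.0307.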

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

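The test of the ABA response between the genotypes was set before the data were examined, while the test of fold change sizes, that of opposite responses, the exchange of spreads and the wider standard errors were chosen after these results were seen. A difference of the ABA response between nup1-1 and Col-0 singled out 3181 genes. By size these were led by AT4G22485 at -9.67, AT2G44130 at -8.06, AT4G22513 at -7.40, AT1G76960 at -6.99 and AT3G16670 at -6.64 on the lower side. AT1G65090 at 4.23, AT3G58450 at 3.85, AT3G14880 at 3.69, AT1G03106 at 3.65 and M10 at 3.43 led the higher side, all on the log2 scale as nup1-1 minus Col-0.

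Of these 10 genes, 9 lost the call with wider standard errors from the deposited p-values, with adjusted p between 0.400 and 0.884, and AT2G44130 stayed at 0.000348; AT1G65090 and AT3G58450 also lost it with the spreads of the genotype comparisons. In nup1-1 these 9 have a value between 0.0102 and 0.263 FPKM in 1 group, where the deposited statistic and p can differ, so their ranking is not a firm basis for picking genes. AT2G44130 belongs to the KMD family of F-box proteins and went from 2.71 to 19.5 FPKM on ABA in Col-0 without a call (q = 0.340), and from 58.1 to 1.57 FPKM in nup1-1, where it was called, in the authors' deposited table.

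The ABA comparison called 9528 genes in nup1-1 and 3174 in Col-0. A smaller spread in the nup1-1 table is a technical explanation, and the median standard error was 0.18 there and 0.24 in Col-0. With the Col-0 spreads put on the nup1-1 fold changes, 7495 genes were still called, against 3328 in Col-0 by the same normal test, which argues against the spread as the whole cause. It may account for part, since the nup1-1 spreads on the Col-0 fold changes raised that count to 4785. In nup1-1 2.19 times as many genes had an absolute log2 fold change of at least 1. That goes with a stronger response for part of the genes, a hypothesis found and tested on the same tables. Of the genes raised in Col-0, 249 had a higher and 284 a lower response in nup1-1. Picking them by their Col-0 change by itself moves that split toward lower.

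In the direct test 22 of 40 photosynthesis genes and 18 of 28 seed storage genes (13 with the wider errors) had the larger response in nup1-1, for the seed list from a median genotype difference of -0.66 untreated to 0.44 on ABA, while COR15A, COR15B, VSP1 and VSP2 rose in Col-0 and fell in nup1-1. The shared Col-0 ABA libraries bear on the genotype comparison on ABA, and not on the direct test, whose tables share no library. They would push the median over the genes lowered in Col-0 to between 0.05 and 0.08, and the observed median was -1.14. Sharing moves that median above 0, so it could not have given a negative value whatever the data. A larger share of arrested seeds or embryos in the nup1-1 samples is a candidate explanation for the larger response. It would send genes with equal untreated levels the same way in both genotypes. Of the genes raised in Col-0 and called in nup1-1, 8.4% fell in nup1-1, between the bounds of 5% and 10% set for that test. That share cannot decide, because a gene may start higher in untreated nup1-1, as COR15A did (6.76-fold). Such a mixture and a changed response in the same cells thus cannot be told apart for the set as a whole.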

How the results depend on the processing

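Among 1047 values recomputed under alternatives, 978 kept their direction and their side of the threshold or moved little. At a threshold of 0.01, added after the data were seen, 31 of 241 calls of named genes in the 4 comparisons were lost, 11 of 57 for ABA in Col-0 and 11 of 38 for genotype in untreated seedlings, among them RAE1, HAI2, SESA3 and OLEO2. A minimum of 1 FPKM changed no named call, which the naming rule fixed in advance, and normal p-values changed none, which the fitted factor made likely. Named genes gave 730 of the 1047 values, so the 978 include alternatives that could hardly fail. Counts of calls moved by over 1.5 times in 10 of 43 cases, mostly under stricter thresholds. With a minimum log2 fold change of 1, 1804 genes were called for ABA in Col-0, 4486 for ABA in nup1-1, 701 for genotype in untreated seedlings and 2781 for genotype on ABA; the genes called in the same direction were 1324 for ABA in both genotypes, and the overlap of the genotype difference between media went from 671 to 236. At a threshold of 0.01, 740 genes were called for genotype in untreated seedlings, 378 were left in that overlap, and the genes whose ABA response differs between genotypes numbered 2039. The nup1-1 spreads on the Col-0 fold changes, an alternative added after the data were seen, gave 4785 calls for ABA in Col-0; the wider spreads, also added later, gave 2931 for the difference of responses.

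The share of calls that were higher in nup1-1 on ABA went from 39.8% to 21.5% with the minimum fold change, so the larger changes were mostly lower. Of 204 recomputed list medians, 3 became weaker, 4 stronger and 1 reversed. With no FPKM filter the median log2 fold change of salicylic acid and defence, Col-0 ABA against Col-0 untreated, went from -0.24 to 0.0263, and the cause was not tested. The median log2 fold change of heat shock proteins and factors, nup1-1 ABA against Col-0 ABA, went from percentile 98.7 to 96.8 with a pseudocount of 0.1 and to 94.3 with no filter. Of 46 recomputed differences of the ABA responses of named genes, 11 became weaker, 9 of them with the wider spreads.

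No paired analysis was possible because the tables carry a single value per group and no replicate number. For the same reason the fits that leave out a replicate, other splits of the samples and the count-based tests that had been planned were not run, so how far single libraries decide any call is not known. Folds of genes near 0 in a group are imprecise, since the deposited p and the statistic can differ there, and the part of depth in this was not tested.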

Other observations

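The tests of clock genes, of library scaling and of linkage to NUP1 were chosen after the genotype differences were seen, and the genes below were named after their values were seen. Single genes higher in nup1-1 in both media included the exportin gene XPO1B, by 1.49 ± 0.23 untreated and 1.65 ± 0.15 on ABA, and AT1G69680, annotated as a putative Ran release factor, by 1.27 ± 0.25 and 1.28 ± 0.17; no list of nuclear transport genes was tested. CEP1, a cysteine endopeptidase gene, was higher by 1.97 ± 0.33 and 2.27 ± 0.24. The sulfur starvation gene ATSDI1 was higher by 2.09 ± 0.30 and 1.84 ± 0.16, and FAR1, a fatty acyl reductase gene of suberin, by 1.92 ± 0.24 and 1.32 ± 0.15.

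Genes lower in both media included MIR163, a microRNA gene, at -3.23 ± 0.32 untreated and -3.76 ± 0.34 on ABA, and QQS at -3.64 ± 0.50 and -4.60 ± 0.55. The B-box genes BBX31 and BBX30 were lower, at -3.09 ± 0.40 and -2.86 ± 0.50 untreated and at -3.36 ± 0.39 and -3.10 (q = 0.00331) on ABA. NEET was lower, at -4.24 ± 0.27 and -3.73 ± 0.29. VSP2, a vegetative storage protein gene, went from 4.99 to 21.2 FPKM on ABA in Col-0 and from 33.2 to 12.4 FPKM in nup1-1, in the authors' deposited table.

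Morning-phased clock genes were lower in nup1-1: 13 of 17 untreated and 14 of 17 on ABA were called lower and none higher, also at an unadjusted p under 0.05, with medians of -1.01 and -1.18. RVE8 (-2.82 ± 0.33), RVE1 (-2.31 ± 0.24), LHY (-1.77 ± 0.37) and CCA1 (-1.17 ± 0.30) were lower untreated, whereas evening-phased genes had medians of 0.11 and -0.25, with 0 of 10 called untreated, against 2 lower at an unadjusted p under 0.05, and 1 higher and 4 lower on ABA. The median of all measured genes was -0.0154 untreated, so the morning-phased genes were lower relative to most genes. Normalization of each table can itself hold that median near 0, so it does not test scaling of the libraries. A different clock phase or hour of harvest is a candidate explanation: the gap between evening and morning medians was 1.12 untreated and 0.93 on ABA, the latter below the 1 set for this test in both media. Harvest times are not given in the sources used here, so phase, harvest and an effect of the genotype on these genes cannot be told apart.

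A hypothesis that untreated genotype differences come mainly from a chromosome region inherited together with the nup1-1 allele was not borne out for a window of 1 Mb. Of 487 tested genes within 1 Mb of NUP1, 6.4% were called, against 6.6% of 19516 tested genes elsewhere. These shares do not test a wider region, and they cannot say whether single genes near NUP1 differ through linkage.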
